A study of Mus musculus with 72 samples.

How the data were processed

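RNA was taken from interfollicular epidermis of back skin, which was separated from the dermis with the enzyme dispase, dissociated, filtered and stored as cell pellets, per the labels' protocols. The deposited files hold whole-number counts of reads per gene, 1 file per library, made by the authors with no normalization. The submitters' processing notes name Trimmomatic, TopHat2 2.1.1 and HTSeq and the builds mm10 and GRCm38, with no parameters, and the library kit and strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart. Each file also holds 5 HTSeq summary lines, which were left out of library sizes and tests. Reads in no gene came to between 12.8% and 20.0% of all lines' reads and ambiguous reads to between 1.16% and 2.60%. The line for reads aligned to several places was 0 in all libraries, so reads shared by near-identical genes were left out or placed before counting, and genes with pseudogenes or close paralogs are reported as uncertain.

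The files hold 46078 genes, of which 45143 were matched by Ensembl identifier to names and coordinates of GENCODE M21 on GRCm38. The other 935 genes held at most 0.0944% of the reads of a library. Of the 108 pairs of libraries within groups, the closest had squared differences of 13.72 times those that sampling alone gives, over genes with a mean count of at least 50, so no pair looked like repeats of 1 library. Genotype, time point and replicate number were taken from the titles. The time points carry an order and no clock hours. Even spacing over 1 day was assumed, and peaks are given on the scale of time points, on which 1 and 7 are the same time.

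Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 18 groups, which left 18515, and libraries were scaled by TMM. The model had 9 coefficients, which are a mean, a cosine and a sine term per genotype with a period of 6 time points, fitted to all 72 libraries so that the genotypes share 1 estimate of the spread. The quasi-likelihood F-test was applied to both cosine terms of a genotype (rhythm), to their difference between genotypes (rhythm difference) and to the difference of means, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The log2 range is the fitted peak-to-trough difference, and its error is the SE of the fit. Depth set the precision of low genes, and levels in CPM use the TMM-scaled library sizes.

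A total of 34 lists with 562 genes were fixed, of which 531 genes were tested, 29 lay below the filter and 2 (Pnp and Krt85) did not match. The lists cover clock activators, clock repressors and PAR bZIP factors, clock-linked outputs, metabolism, stress responses, cell division, DNA repair, layers of the epidermis and markers of hair follicle, glands and other cells of skin. Differences of level by list were tested with camera of limma 3.58.1 with a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether genes of a list move on balance in 1 direction. Rhythm by list was tested with a one-sided Fisher's exact test against all genes tested. Adjustment was over the 34 lists within a comparison. Genes of a list are not independent, which the Fisher test does not allow for.

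Genes named in the text follow a rule. Part (a) takes Arntl and the measured members of the 3 clock lists in every comparison. Part (b) takes, for the rhythm of each genotype and each rhythm difference, the 10 protein-coding genes of smallest p outside (a). Part (c) takes, for each difference of means, the 10 largest rises and 10 largest falls among protein-coding genes with an adjusted p under 0.05, a mean of at least 5 CPM over both genotypes and the same direction at all 6 time points. Part (d) takes up to 4 members of smallest p of each list. Symbols starting with Gm and a digit or ending in Rik were left out of (b) and (c) where no biotype was given, and fewer genes may be named, in the order of the ranking. A few genes that the rule takes are not reported here. Genes named to describe libraries (mt-Co1, mt-Nd1 and Krt14) and 2 pseudogenes were chosen after their values were seen.

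The tests were tested on simulated data with 18304 genes in 72 libraries drawn from the real means. For the WT rhythm 69 of 100 genes with a 1.5-fold and 100 of 100 with a 3-fold range were recovered, with 5% false calls and a median peak error of 0.0521 time points at 3-fold. For the difference of means between KO and WT 99 of 100 genes at 1.5-fold and 100 of 100 at 3-fold were recovered, with 5.69% false calls. For the rhythm difference between KO and WT 49 of 100 and 90 of 100 were recovered, with 5.44% false calls. The changed genes had mean counts over 100, and the planted rhythms were exact cosines. No sets and no libraries in doubt were simulated, so these shares need not hold in the real data.

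The design, the lists, the rule for named genes and most alternatives were set before the data were examined. These alternatives are DESeq2 size factors, no filter, a filter of 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, the older quasi-likelihood fit with robust spread, time point as a factor, a fit of only the genotypes compared, the replicate number as a block, an adjusted p under 0.01, a fold of at least 1.5, peaks within 0.5 time points or with no limit, and leaving out each library and each replicate number. Alternatives added after the data were seen leave out 2 libraries with little Krt14, 3 libraries of time point 3, all 5, or time point 4, add the processing set as a term, test time points within a set, or use replicate blocks within each time point. The processing sets are 2 sets of libraries told apart by reads in mt-Co1 relative to mt-Nd1, and the labels name no batch.

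Positions of libraries between groups used the 50 protein-coding genes of smallest p between the groups with a fold of at least 1.5, outside the clock lists, chosen at the other 5 time points and without the 5 libraries in doubt. Reads that could be shared between genes were gauged by 31-base words, and a gene was counted where at least 20% of its words also lay in another gene. Random lists numbered 10000, permutation tests used 1e+05 resamples, and at most 100 other splits of the libraries were refitted per result. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.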

Results

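The series holds 72 RNA-seq libraries of mouse interfollicular epidermis, the part of the epidermis between the hair follicles, taken from back skin. The labels give 3 genotypes. K14-Cre mice served as wild type (WT). Bmal1-stopFL mice (KO) carry a stop cassette that silences Bmal1, the core clock transcription factor encoded by Arntl. Bmal1-stopFL mice with K14-Cre (RE) regain Bmal1 where the keratin 14 promoter is active, in the epidermis and other stratified epithelia. Each genotype was sampled at 6 time points of a light and dark day, with 4 females at each, which makes 18 groups of 4 libraries and 24 libraries per genotype. The design text asks which part of the daily epidermal transcriptome remains when only the epidermal clock works. Libraries held between 2.96e+07 and 4.95e+07 reads counted in genes, with a median of 3.69e+07 in WT, 3.77e+07 in KO and 3.88e+07 in RE, and between 20244 and 23582 genes were detected in a library. The p-values rest on the spread between mice of a group together with the misfit of group means to the cosine.

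Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126, plus strand, GRCm38) was at 31.3 ± 2.98 CPM (reads scaled to library size, SD, n = 24) over the 6 time points in KO and did not pass the test for a daily rhythm there (adjusted p = 0.842). In WT it went from 130 ± 18.5 CPM at time point 1 to 27 ± 3.08 CPM at time point 4 and back to 103 ± 8.93 CPM at time point 6 (SD, n = 4). In RE it went from 99.1 ± 10.4 CPM at time point 1 to 50.4 ± 15.8 CPM at time point 3 and 79.9 ± 17.2 CPM at time point 6. The mean over the day fell in KO against WT (log2 change -1.09 ± 0.09, SE, edgeR adjusted p = 6.37e-16) and did not pass the test between RE and WT (0.09 ± 0.08, adjusted p = 0.718). Counts over the gene do not show which exons were read, so the remaining Arntl reads in KO do not give the level of intact transcript. In the library labelled KO time point 3 replicate 1, Arntl was at 21 CPM, Nr1d1 at 253 CPM, Dbp at 132 CPM and Npas2 at 6.44 CPM. On a scale from WT (0) to KO (1), made from 50 genes outside the clock lists that best separate these groups at other time points, this library lay at -0.0338, while the other 23 KO libraries lay between 0.808 and 1.1. On the matching scale from WT (0) to RE (1), the library labelled WT time point 3 replicate 2 lay at 0.77 and the library labelled RE time point 3 replicate 2 at -0.23. The labels were kept as given.

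**Figure D1:**
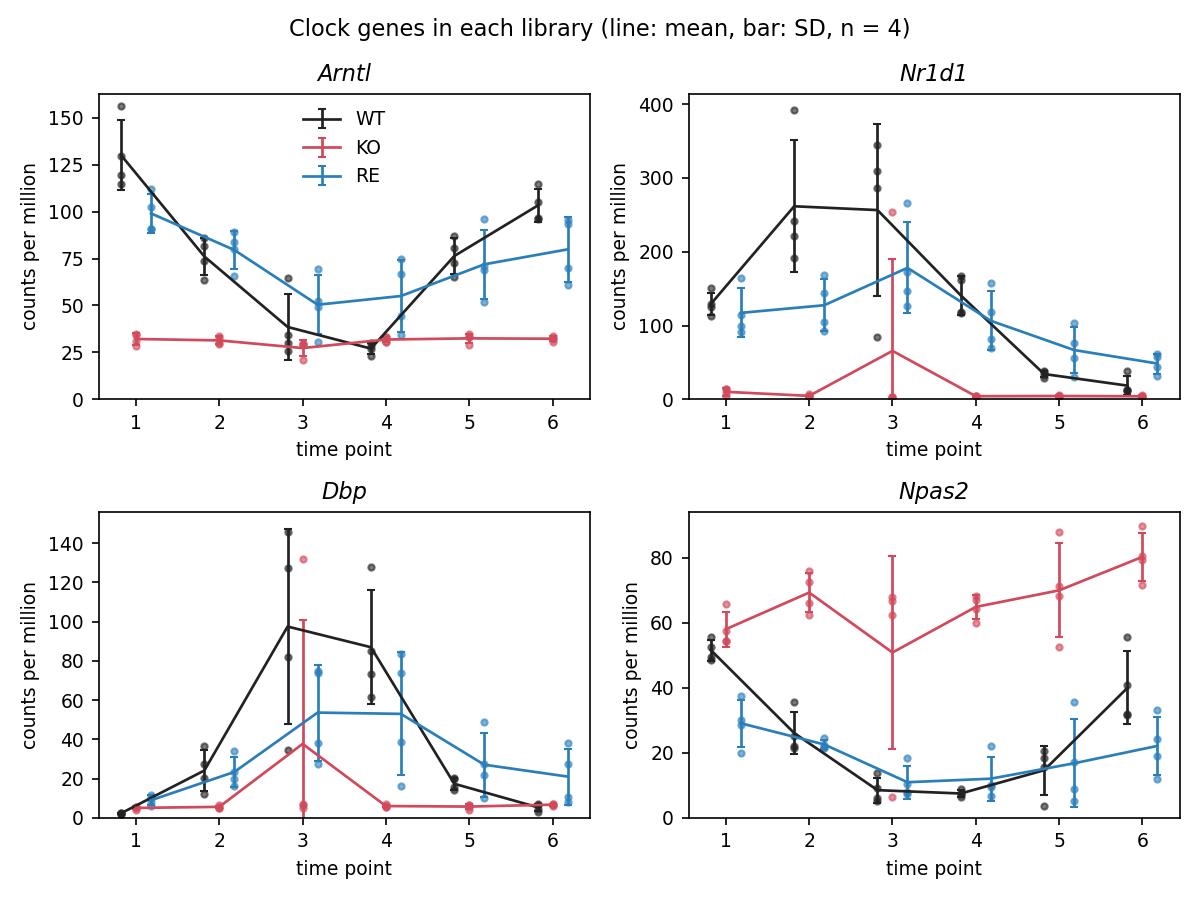
Arntl, Nr1d1, Dbp and Npas2 in CPM in each library against time point, coloured by genotype, with lines for the means and bars for the SD (n = 4). The KO libraries stay near 31.3 CPM of Arntl, and the library labelled KO time point 3 replicate 1 stands apart in Nr1d1 (253 CPM) and Dbp (132 CPM).

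**Figure D2:**
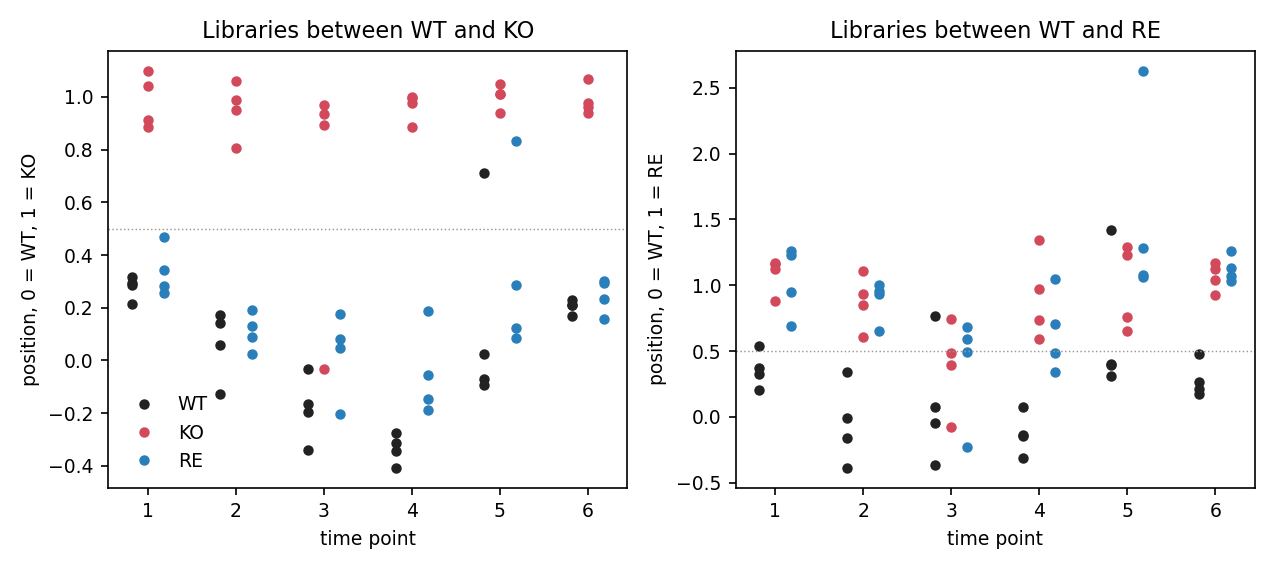
Position of each library between WT (0) and KO (1) on the left and between WT (0) and RE (1) on the right, against time point, with a dotted line at 0.5. The library labelled KO time point 3 replicate 1 lies at -0.0338 among the WT libraries on the left.

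Libraries also fell into 2 sets that follow neither genotype nor time point alone. They are called processing sets only as a name, since the labels give no batch. The log2 ratio of reads in mt-Co1 to reads in mt-Nd1, both encoded in the mitochondrial genome, lay between -3.75 and -3.02 in 40 libraries (WT time points 1 to 4, KO and RE time points 1 to 3) and between -6.03 and -5.09 in the other 32 libraries. No group was split between the sets, and the gap between them was 1.34 against 0.20 for the next largest. With the set as a term in the model, 3013 genes changed between the sets beyond what genotype and a daily cosine accounted for, of which 661 were at least 2-fold lower and 67 at least 2-fold higher in the 32 libraries. In KO and RE the sets divide the first from the last 3 time points, and WT time point 4 lies in another set than KO and RE time point 4. Values with the set as a term, an alternative chosen after the data were seen, therefore stand beside the pooled ones. In KO and RE this term overlaps with a cosine that peaks near time point 2 or 5. A call lost with the term thus does not tell a step between the sets from a daily rhythm. Counts with the term are also hard to compare between genotypes, since the sets divide WT elsewhere. Separately, the library labelled WT time point 5 replicate 4 and the library labelled RE time point 5 replicate 3 held at most 343 CPM of Krt14, the keratin of basal keratinocytes, against at least 2510 CPM in the other 70. These 2 and the 3 libraries of time point 3 named above are the 5 libraries in doubt.

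**Figure D3:**
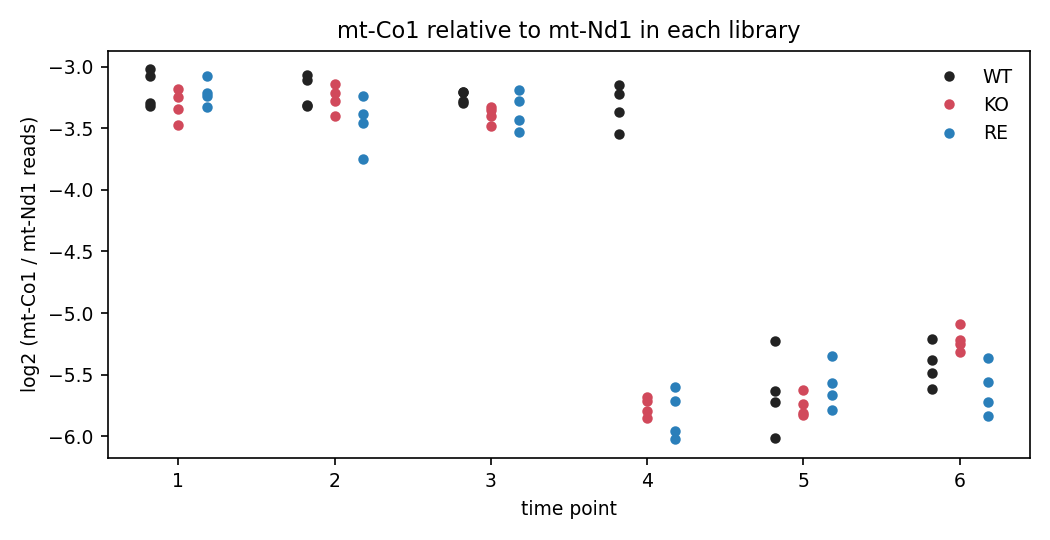
Log2 ratio of reads in mt-Co1 to reads in mt-Nd1 in each library against time point, coloured by genotype. The 40 libraries of the first set lie at or above -3.75, and the other 32 lie at or below -5.09.

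In WT, most genes of the 2 core clock lists changed over the day. Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203), a clock output transcription factor, went from 2.31 ± 0.27 CPM at time point 1 to 97.5 ± 49.8 CPM at time point 3 (SD, n = 4). Per2, a repressor in the clock loop, went from 5.05 ± 4.05 CPM at time point 1 to 144 ± 12.9 CPM at time point 4. Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236), which pairs with Bmal1 in place of Clock, did the opposite, with 51.6 ± 3.22 CPM at time point 1 and 7.48 ± 1.01 CPM at time point 4. Fitted log2 peak-to-trough ranges were 5.24 ± 0.56 for Dbp with a peak at 3.48 on the time point scale, 4.63 ± 0.43 for Per2 (peak 4.22) and 3.82 ± 0.69 for Nr1d1 (peak 2.57). Their adjusted p were 6.46e-10, 1.02e-11 and 7.12e-05 (SE, n = 24, edgeR quasi-likelihood test). Npas2 ranged 2.99 ± 0.33 (peak 6.74) and Arntl 2.13 ± 0.17 (peak 6.61), with adjusted p of 6.97e-10 and 1.15e-13. Rora (0.22, adjusted p = 0.289) did not pass. Nr1d1 no longer passed with the set as a term (1.47, adjusted p = 0.394), but did with the 5 libraries in doubt also left out (2.72, 1.8e-05).

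Outside the clock lists, the genes of smallest p in WT were Rabl6, a Rab-like GTPase (log2 range 0.62 ± 0.06, peak 4.60, adjusted p = 1.02e-11), the phosphoinositide phosphatase Mtmr2 (0.83 ± 0.08, peak 2.59) and Ccni (1.15 ± 0.11, peak 2.35). Next came Sec22c of the secretory pathway (0.80 ± 0.08, peak 4.29), Naa60 (0.73 ± 0.07, peak 4.52) and Sod2, the mitochondrial superoxide dismutase (0.80 ± 0.08, peak 4.57). Sod2 went from 50.7 ± 5.28 CPM at time point 2 to 86 ± 12.1 CPM at time point 5. In total 6332 of 18515 genes tested changed over the day in WT (34.2%), with a median peak-to-trough fold of 1.51, and 1800 of them ranged more than 2-fold. Peaks lay nearest time points 1 and 5 for 1552 and 1409 genes, and nearest time point 6 for 550. Adding the set as a term left 4831 genes, 3783 of them shared with the first count.

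Cell division genes changed over the day in WT, with different mean peaks for mitosis and S phase. Of 23 measured G2 and mitosis genes 22 passed (23 adjusted over the list alone), with a mean peak at 6.84 and a median log2 range of 1.43. Cdc20, the activator of the anaphase-promoting complex, ranged 1.99 ± 0.31 (peak 1.47) and went from 12.2 ± 1.78 CPM at time point 1 to 3.06 ± 1.79 CPM at time point 5 (SD, n = 4). Cenpa, the centromeric histone, ranged 1.57 and Ube2c 1.92. Of 23 S phase and replication genes 16 passed (18 adjusted over the list alone) with a mean peak at 4.09, led by the replicative helicase subunits Mcm2 (1.57 ± 0.29, from 24.3 ± 2.7 CPM at time point 1 to 75.4 ± 10.5 CPM at time point 4), Mcm6 (1.23) and Mcm3 (1.49). One-sided Fisher tests against all genes tested gave adjusted p of 2.88e-08 for G2 and mitosis and 0.00648 for S phase, and 8.55e-06 and 0.00375 with the set as a term. With that term and without the 5 libraries in doubt, 2 of which lay at time point 5, 23 and 20 genes passed (1.15e-10 and 1.09e-06).

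Other lists that passed in WT were the clock repressors and PAR bZIP factors with 12 of 13 genes (12 adjusted over the list alone, adjusted p = 0.000385) and glycolysis with 13 of 18 (14, 0.0095). So did melanocyte markers with 7 of 8 (7, 0.0208), sebaceous gland with 9 of 12 (9, 0.0245) and the unfolded protein and integrated stress response with 11 of 16 (13, 0.0245). Melanocyte genes peaked close together, with 7 of 7 within 1 time point of 1.15, and had a median log2 range of 3.62. They include Tyr (5.18 ± 0.82), Tyrp1 (4.10) and Dct (3.62), the enzymes of melanin synthesis. Rhythmic genes of the unfolded protein and integrated stress response peaked near 5.88 on average, and the chaperones Hsp90b1 and Calr ranged 0.62 and 0.65. The glycolysis genes Aldoa (1.28) and Tpi1 (0.74) peaked at 2.33 and 2.29. Glycolysis and sebaceous gland no longer passed with the set as a term. Stressed keratinocyte genes (9 of 12, adjusted p = 0.00375), clock activators (5 of 6, 0.0214), and fatty acid oxidation, hair follicle and Langerhans cell genes (9 of 14 each, 0.0126) then did. Of these 5 lists stressed keratinocytes lost the call with the 5 libraries in doubt also left out (7 of 12, adjusted p = 0.147). Aldoa and Tpi1 then gave 0.29 (adjusted p = 0.106) and 0.18 (0.31).

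In KO, most clock genes did not pass the test for a daily rhythm. Fitted log2 ranges were 0.18 ± 0.17 for Arntl, 0.40 for Npas2, 0.36 for Per2, 0.37 for Cry1 and 0.10 for Cry2, with adjusted p between 0.686 and 0.882. Nr1d1 (3.47 ± 0.69, adjusted p = 6.76e-05), Nr1d2 (1.68 ± 0.37, 0.000538), Dbp (2.25 ± 0.57, 0.00204) and Per3 (1.46 ± 0.37, 0.00545) passed the test. Without the 5 libraries in doubt, which include the one labelled KO time point 3 replicate 1, these 4 genes gave 1.12, 0.12, 0.16 and 0.20 and adjusted p of 0.108, 0.903, 0.96 and 0.86. In the other KO groups Nr1d1 lay between 4.13 and 10.2 CPM and Dbp between 5.05 and 6.71 CPM.

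Among other genes in KO, those of smallest p were Mtmr2 (0.85, peak 2.13), the ATP synthase subunit Atp5o (2.18 ± 0.20, peak 1.94) and the ribosomal proteins Mrps14 (1.12) and Rpl4 (2.15 ± 0.20, peak 2.01). They were followed by 1110004F10Rik (1.62), Rnf7 (1.60), the cytochrome oxidase subunit Cox7b (2.42 ± 0.23), Gucd1 (0.99 ± 0.10) and the ribosomal protein Rps21 (5.23 ± 0.49). Each of these lost its call with the set as a term, where Atp5o gave 0.26 (adjusted p = 0.428), Rpl4 0.02 (0.994), Cox7b 0.16 (0.786) and Rps21 0.15 (0.967). Rpl4 and Rps21 are families with many pseudogenes, so their counts are uncertain. In total 1425 genes passed in KO (7.7%), 648 of them with a peak nearest time point 2 and 415 nearest time point 5. Adding the set as a term left 540, of which 207 were shared with the 1425. Within the sets 338 genes changed among time points, of which 135 were shared with the 1425.

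By lists, oxidative phosphorylation (20 of 75, 21 adjusted over the list alone, adjusted p = 2.1e-05), glycolysis (7 of 18, 7, 0.004) and skeletal muscle (4 of 9, 4, 0.0364) passed in KO. These 3 lists no longer passed with the set as a term, though glycolysis did with the 5 libraries in doubt also left out (5 of 18, adjusted p = 0.0226). Instead stressed keratinocyte (6 of 12, adjusted p = 1.62e-05) and granular layer genes (5 of 24, 0.00945) did. Sprr2d (7.37 ± 1.08, peak 1.08, at a mean of 0.32 CPM), Sprr1b (3.77, peak 6.64) and Lor (2.12 ± 0.46, peak 6.65), which encode precursors of the cornified envelope, passed in both fits, though limma-voom did not call Sprr2d. Adjusted over the list alone, 9 of 12 sebaceous gland (0 over all genes), 9 of 14 Langerhans cell and macrophage (1) and 8 of 12 stressed keratinocyte genes (4) passed in KO. No G2 and mitosis gene passed, with Cdc20 at 0.91 ± 0.31 (adjusted p = 0.139), and of the S phase genes Slbp passed (0.57 ± 0.16, adjusted p = 0.0464).

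In RE, clock activators and repressors again included genes that changed over the day. Per2 ranged 2.50 ± 0.40 (peak 4.21, adjusted p = 1.11e-05), from 13 ± 4.76 CPM at time point 1 to 89.6 ± 40.3 CPM at time point 4 (SD, n = 4). Dbp ranged 2.23 ± 0.54 (peak 3.73, 0.00558) and Tef 1.31 ± 0.24 (peak 3.95, 0.000157). Npas2 ranged 1.37 ± 0.32 (peak 6.77, 0.0053), Arntl 0.89 ± 0.17 (peak 6.67, 0.000285) and Cry2 0.66 ± 0.11 (peak 3.99, 1.11e-05). These ranges were below those of WT, but the difference passed its own test for none of these 6 genes (smallest adjusted p 0.0556, Arntl). It passed for 5 of the 6, all but Per2 (0.0926), without the 5 libraries in doubt. Nr1d1 (1.63 ± 0.63, adjusted p = 0.158) and Nr1d2 (1.08, 0.0755) did not pass, and without the 5 libraries in doubt both did (1.52, 0.0023 and 1.02, 2.15e-05). Cry1 gave 1.26 (adjusted p = 0.0537) with the set as a term, and 1.59 (0.000912) with the 5 libraries in doubt also left out.

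Other genes of smallest p in RE were again Mtmr2 (0.90, set as a term 0.26), Rpl4 (2.24, 0.07), Gucd1 (1.03, 0.15), Atp5o (2.13, 0.16), Aldoa (1.58 ± 0.15, 0.31) and Ccni (1.11, 0.21), and all 6 lost their call with the set as a term. In total 2494 genes passed in RE (13.5%), and 569 with the set as a term, 330 of them shared. Within the sets 731 genes changed among time points. Using only the compared genotypes gave 1615 of 17708 genes tested. Testing only genes of higher counts gave 1531 of 11720, against 2494 of 18515 in the main fit. Hair shaft (9 of 15, 11 adjusted over the list alone, adjusted p = 0.000568), skeletal muscle (7 of 9, 7, 0.000568) and clock repressors (7 of 13, 9, 0.00737) passed by lists. Granular layer (9 of 24, 13, 0.0237) and oxidative phosphorylation (19 of 75, 20, 0.0286) also did. Hair shaft, muscle and oxidative phosphorylation did not pass with the set as a term. Clock repressors (7 of 13) and granular layer genes (9 of 24) did, both with adjusted p = 6.2e-07, as did stressed keratinocyte (4 of 12, 0.00407) and G2 and mitosis genes (4 of 23, 0.0417). Hrnr (1.37 ± 0.26, peak 5.67) and Alox12b (1.45, peak 5.76), of the late epidermal barrier, led the granular genes. Heat shock (5 of 16, 9 adjusted over the list alone) and immediate early genes (3 of 21, 8) did not pass as lists. Of the G2 and mitosis genes 5 of 23 passed in RE (17 adjusted over the list alone, adjusted p = 0.495 by Fisher's test), with a mean peak at 6.95. With the set as a term and without the 5 libraries in doubt 12 of 23 did (1.63e-08). The 5 were led by Cdc20 (1.76 ± 0.31, peak 1.43, adjusted p = 8.77e-05) and the mitotic kinase Plk1 (1.55, peak 1.08).

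**Figure D4:**
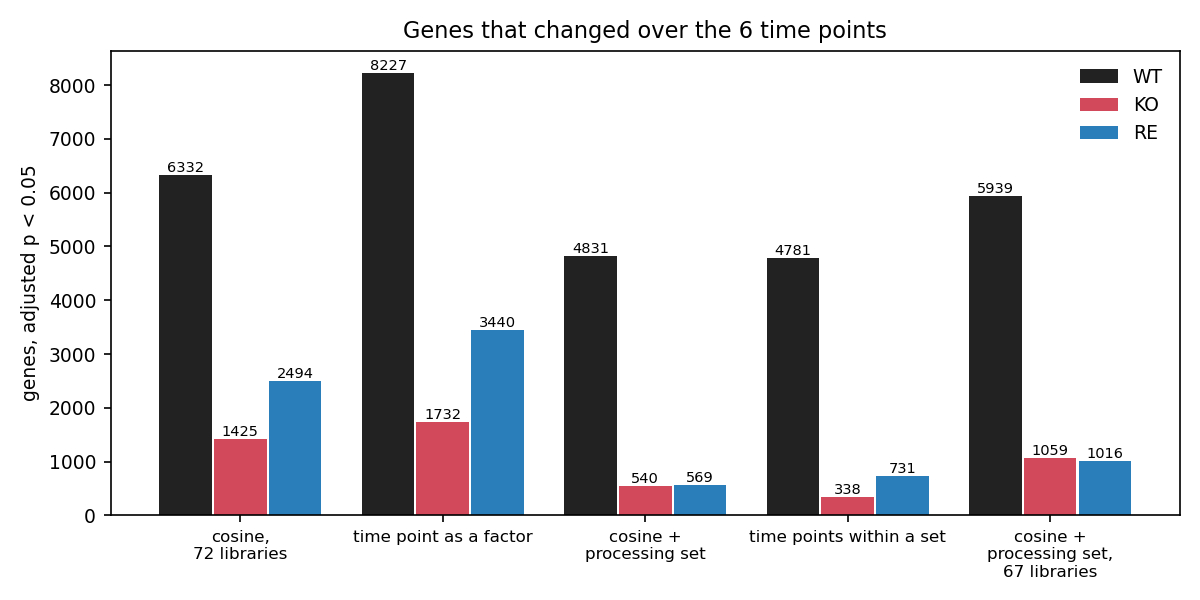
Number of genes that passed the test for change over the 6 time points in WT, KO and RE under 5 models, as bars from 0. The count is highest in WT under each model, and the counts of KO and RE go from 1425 and 2494 to 540 and 569 with the processing set as a term.

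The question of the design, which daily changes remain with the epidermal clock alone, was also put as a count of genes that passed in WT and in a second genotype with peaks within 1 time point. This held for 1984 genes in RE, where independent lists would share 284, and for 1146 in KO, where they would share 162. Independent lists do not allow for the sets, which divide the time points alike in KO and RE and similarly in WT. The excess over them therefore does not show retained daily rhythm alone. Median folds were 2.57 in WT, 1.96 in RE and 1.14 in KO for G2 and mitosis genes, 1.84, 1.39 and 1.14 for S phase genes and 4.35, 2.11 and 1.78 for clock repressors. With the set as a term clock repressors gave 2.94 in WT, 2.94 in RE and 1.95 in KO, and S phase genes gave 1.91, 1.32 and 1.3. Clock repressors gave 5, 2.03 and 1.15 without the 5 libraries in doubt, and with the set also as a term 6.33, 2.31 and 1.78. The counts of genes were 514 in RE and 441 in KO with the set as a term, for which no number from independent lists was computed.

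Rhythms differed between KO and WT in 249 genes by a direct test of the cosine terms (2474 at an unadjusted p under 0.05). Among clock genes Cry2 (adjusted p = 2.91e-08), Per2 (8.09e-08), Arntl (4.26e-07), Tef (7.79e-06), Npas2 (0.00031), Per3 (0.00297), Cry1 (0.00419), Dbp (0.0396) and Ciart (0.0396) passed, each with the larger range in WT. Nr1d1 (0.946) and Nr1d2 (0.815) did not, and without the 5 libraries in doubt both did (2.35e-07 and 1.98e-07). The other genes of smallest p were Sod2 (0.08 in KO against 0.80 in WT, adjusted p = 3.55e-06), the MHC class II regulator Rfx5 (0.15 against 0.81, 3.4e-05), Rabl6 (0.05 against 0.62, 3.4e-05) and the methionine synthase reductase Mtrr (0.20 against 0.66, 6.44e-05). Next were the fatty acid oxidation enzyme Acadl (0.06 against 0.71, 0.000103), the folate enzyme Mthfd1l (0.34 against 2.77, 0.000134), Sec22c (0.14 against 0.80, 0.000161) and Ttc9 (0.27 against 2.04, 0.000206). By lists, 7 of 13 clock repressors passed (9 adjusted over the list alone), 3 of 6 activators (4), 2 of 14 fatty acid oxidation genes (4) and 2 of 19 antioxidant genes (6). None of 23 G2 and mitosis genes (10) or of 23 S phase genes (4) did.

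That count was sensitive to the libraries used. It was 132 without WT time point 4 replicate 3, 149 without WT time point 4 replicate 4, 162 without KO time point 1 replicate 1 and 141 without KO time point 1 replicate 4. It was 155, 146 and 151 without KO time point 4 replicates 2, 3 and 4, and 411 without RE time point 5 replicate 3. It was 895 without the 5 libraries in doubt, among them all 249 genes, and 31 without time point 4. Time point as a factor gave 541 genes and DESeq2 386. The factor can also take up a step between the sets at time point 4, where KO lies in another set than WT. With the set as a term 236 genes passed, 99 of them shared. Dbp (adjusted p = 0.0652) and Ciart (0.53) then no longer passed, but did with the 5 libraries in doubt also left out (5.49e-11 and 0.000722), while Sod2, Rfx5, Rabl6, Mtrr and Acadl kept their calls.

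Between RE and WT the rhythm test passed for 5 genes (1152 at an unadjusted p under 0.05). Ltf, which encodes lactoferrin, ranged 4.37 with a peak at 3.95 in RE and 4.63 with a peak at 1.55 in WT (adjusted p = 0.0165), and the hair keratin-associated Krtap11-1 ranged 5.13 and 2.04 (0.0316), both at low counts. Rps15a-ps7 (0.0226) and Gm16148 (0.0415) are pseudogenes whose reads can come from their parent genes, and they are named because the count is small, after their values were seen. Arntl missed the threshold (adjusted p = 0.0556). With the set as a term 1 gene passed, and Ltf (0.207) and Krtap11-1 (0.0879) no longer did. By lists, 1 of 6 clock activators (3 adjusted over the list alone) and 0 of 13 clock repressors (7) passed. Without the 5 libraries in doubt 99 genes passed, with Dbp (5.11e-05), Arntl (4.65e-05), Per3 (0.000217), Tef (0.00052), Cry2 (0.00229), Ciart (0.00487), Npas2 (0.00756), Nr1d1 (0.0102), Nr1d2 (0.0131) and Cry1 (0.0248) among them, but not Per2 (0.0926).

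Single libraries moved this count of 5 in both directions. It was 44 without WT time point 1 replicate 1, 16 without WT time point 1 replicate 2, 30 without RE time point 2 replicate 2 and 17 without RE time point 3 replicate 2. It was 14 without KO time point 3 replicate 1, 11 without RE time point 5 replicate 3 and 8 without WT time point 6 replicate 3. It was 3 without WT time point 2 replicate 1, WT time point 4 replicate 2, RE time point 1 replicate 2, RE time point 1 replicate 3, RE time point 4 replicate 3 or RE time point 6 replicate 2. It was 2 without WT time point 4 replicate 3, WT time point 4 replicate 4 or RE time point 4 replicate 4, 1 without WT time point 2 replicate 2, and 0 without time point 4. Treating time point as a factor gave 336 genes, DESeq2 22, no filter 3, limma-voom and the older robust fit 2 each, and a filter of 5 CPM in 4 libraries 1. With time point as a factor, a step between the sets can be called at time point 4, where RE lies in another set than WT. The 336 genes are therefore not all shown to differ in rhythm.

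Between RE and KO no rhythm difference passed, with 0 genes by edgeR, DESeq2 and limma-voom, and 526 genes at an unadjusted p under 0.05. Per2 ranged 2.50 in RE and 0.36 in KO, but the difference itself did not pass over all genes. Outside the clock lists the smallest p belonged to Defb35 and to the glucocorticoid-induced chaperone Fkbp5, both with adjusted p = 0.588. Adjusted over the list alone, 2 of 6 clock activators, 3 of 13 clock repressors and 2 of 15 glucocorticoid response genes passed. The count was 2 without RE time point 1 replicate 4 and 1 without RE time point 5 replicate 3. Without the 5 libraries in doubt Per2 alone passed (adjusted p = 0.0171).

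Mean levels over the day differed widely between KO and WT, and clock genes were among the most changed. Nr1d1 (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), a repressor of Arntl, fell to 15.6 CPM in KO from 140 CPM in WT (log2 change -3.26 ± 0.34, SE, n = 24, adjusted p = 1.43e-11). Nr1d2 fell by 2.35 ± 0.19 (1.42e-15), Per3 by 1.59 ± 0.19 (6.49e-10), Ciart by 1.16 ± 0.26 (0.000713) and Dbp by 1.09 ± 0.28 (0.0026). Npas2 rose by 1.76 ± 0.16 (1.26e-13), the repressor Cry1 by 1.46 ± 0.12 (3.45e-15) and Clock by 0.24 ± 0.04 (1.81e-05). The KO mean includes the library labelled KO time point 3 replicate 1, and without the 5 libraries in doubt the changes were -4.39 for Nr1d1 and -1.78 for Dbp. Per1 fell by 0.42 (adjusted p = 0.0337), a call lost with the set as a term (0.168).

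Outside the clock, the largest rises in KO were those of Abhd12b (1.44 ± 0.12, from 16.8 CPM in WT to 44.7 CPM), F3, the tissue factor that starts coagulation (1.39 ± 0.26), Ttc9 (1.39 ± 0.10) and Slc46a2 (1.35 ± 0.13). Then came Epgn, an epidermal growth factor receptor ligand (1.35 ± 0.22, from 103 to 258 CPM), and Scd2, a fatty acid desaturase (1.28 ± 0.15). The largest falls were those of the gasdermin Gsdmc (-2.38 ± 0.22, from 20.9 to 4.01 CPM), the collagen receptor Ddr2 (-2.22 ± 0.18, from 41.8 to 8.87 CPM), Pde1b (-1.82), Crispld2 (-1.62 ± 0.24) and the neurotrophin receptor Ngfr (-1.45 ± 0.20). The largest adjusted p among these genes was that of F3 (3.83e-05), and none of them lost its call under the alternatives. In total 1666 genes rose and 2093 fell. Without the 5 libraries in doubt 2631 rose, and without time point 4 the counts were 778 and 1063.

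By lists, cholesterol synthesis genes were higher in KO, with 13 of 19 raised and 1 lowered (15 and 1 adjusted over the list alone). The enzymes Lss (0.47 ± 0.08), Sc5d (0.42 ± 0.07), Dhcr7 (0.42 ± 0.07) and Idi1 (0.50 ± 0.09) led them, and camera gave an adjusted p of 5.18e-09 (adjusted p = 0.634 with an estimated correlation). Spinous keratinocyte genes rose in 9 of 16 cases and fell in none (11 and 0 adjusted over the list alone, camera 1.79e-07, and adjusted p = 0.634 with an estimated correlation), with the metallothionein Mt4 at 1.10 ± 0.09 and the suprabasal keratin Krt1 at 0.47 ± 0.09. Granular layer genes rose in 5 and fell in 2 of 24 (5 and 2, camera 0.0158, and adjusted p = 0.719 with an estimated correlation), with Hrnr at 0.71 ± 0.13 and Ivl at 0.52 ± 0.12. Clock repressors rose in 1 and fell in 8 of 13 (2 and 10, camera 1.89e-06, and adjusted p = 0.281 with an estimated correlation). Clock-linked outputs fell in 4 of 8 (4, camera 0.0184, and adjusted p = 0.687 with an estimated correlation), with Klf9 at -0.67 ± 0.14 and Tspan4 at -0.42 ± 0.07.

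Further lists were lower in KO. Glycolysis genes fell in 7 and rose in 1 of 18 (12 and 1 adjusted over the list alone, camera 0.00681, and adjusted p = 0.687 with an estimated correlation), among them Tpi1 (-0.30 ± 0.06), Pkm (-0.26 ± 0.07) and the lactate exporter Slc16a3 (-0.59 ± 0.15). Growing hair shaft genes fell in 11 and rose in 1 of 15 (12 and 1, camera 0.00118, and adjusted p = 0.687 with an estimated correlation), with the inner root sheath keratins Krt73 (-4.60 ± 0.74) and Krt71 (-2.87 ± 0.58) among those that fell. Melanocyte genes fell in 4 of 8 (5, camera 0.00396, and adjusted p = 0.687 with an estimated correlation), with Kit at -1.09 ± 0.22. Sebaceous gland genes fell in 6 of 12 (7, camera 0.0123, and adjusted p = 0.719 with an estimated correlation), with Mgst1 at -0.58 ± 0.14. Interferon response genes fell in 5 of 21 with 1 raised (8 and 1, camera 0.0166, and adjusted p = 0.719 with an estimated correlation), with Bst2 at -0.65 ± 0.10 and Ddx58 at 0.58 ± 0.06. With the set as a term glycolysis (0.0804), melanocyte (0.0562) and clock-linked outputs (0.0906) did not pass. No list of the 3 mean comparisons held its call with an estimated correlation. Fry called 8 lists between KO and WT. It did not call granular layer (adjusted p = 0.126), sebaceous gland (0.0617) or interferon response genes (0.108).

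The remaining 24 lists did not pass by camera between KO and WT, though fry called clock activators higher (adjusted p = 0.00108). Heat shock (adjusted p = 0.0219) and oxidative phosphorylation (0.0329) were called higher by camera with the set as a term, and clock activators (0.0229) and fatty acid synthesis (0.0192) without the 5 libraries in doubt. Genes raised and lowered were 3 and 2 of 6 clock activators, 0 and 1 of 2 cold-inducible genes, 2 and 1 of 16 heat shock genes, 1 and 4 of 15 glucocorticoid response genes and 3 and 1 of 9 fatty acid synthesis genes. They were 3 and 2 of 14 fatty acid oxidation genes, 6 and 5 of 75 oxidative phosphorylation genes and 3 and 4 of 19 antioxidant genes. For S phase they were 1 and 0 of 23, for G2 and mitosis 0 and 0 of 23, for DNA repair 2 and 1 of 22, and for p53 targets 1 and 2 of 15. They were for basal keratinocytes 1 and 0 of 14, for stressed keratinocytes 0 and 2 of 12, for immediate early genes 5 and 0 of 21 and for the unfolded protein response 1 and 1 of 16. Among markers of other structures and cells they were 1 and 1 of 14 for hair follicle, 0 and 1 of 14 for Langerhans cells and macrophages and 1 and 4 of 12 for epidermal T cells. They were 2 and 0 of 13 for fibroblasts, 0 and 1 of 6 for endothelial cells, 1 and 0 of 9 for skeletal muscle, and 0 and 0 of 3 and of 4 for adipocytes and red blood cells. Adjusted over the list alone, these counts differed for activators (4 and 2), glucocorticoid response (1 and 6), fatty acid oxidation (3 and 3), oxidative phosphorylation (4 and 5), p53 targets (2 and 2), unfolded protein response (0 and 0), hair follicle (2 and 2) and endothelial cells (0 and 2). Median and mean had opposite signs for oxidative phosphorylation (0.02 and -0.01), fatty acid oxidation (-0.03 and 0.04), hair follicle (0.04 and -0.02) and skeletal muscle (0.06 and -0.07). Camera's direction went against the median for fatty acid oxidation, adipocytes (-0.14) and red blood cells (-0.16).

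Few genes differed in mean level between RE and WT, and no clock gene did (Nr1d1 0.00, adjusted p = 0.997, and Dbp 0.47 ± 0.27, 0.495). The suprabasal keratin Krt2 (ENSMUSG00000064201, chromosome 15, 101810689 to 101818169) was higher in RE, with 11.2 CPM against 5.11 CPM (1.10 ± 0.14, adjusted p = 1.7e-07). The protease inhibitors Stfa3 (0.85 ± 0.22, 0.0474) and Stfa1 (0.78, 0.0307) and Lrrc32, which anchors latent TGF-beta at the cell surface (0.83 ± 0.14, 0.000198), also rose. So did Wfdc21 (0.77, 0.0274), the Wnt antagonist Nkd2 (0.70 ± 0.15, 0.00927), Nsg1 (0.68 ± 0.08, 6.28e-08) and Mt4 (0.54 ± 0.09, 0.000235). Lower in RE were Npr3, the natriuretic peptide clearance receptor (-0.87 ± 0.21, 0.0294), Ndufa4l2, a mitochondrial protein induced by low oxygen (-0.80 ± 0.12, 77.4 against 135 CPM, 3.14e-05), Slc16a3 (-0.69 ± 0.16, 0.015) and Wnt16 (-0.67 ± 0.17, 0.0392). So were the angiogenic factor Vegfa (-0.60 ± 0.13, 0.00927), Rasgrf1 (-0.56, 0.0223), Afap1l1 (-0.54, 0.0285) and Pfkfb3, a regulator of glycolysis (-0.53 ± 0.14, 0.0412). Stfa3 (0.109), Wnt16 (0.119), Vegfa (0.0657), Rasgrf1 (0.104) and Pfkfb3 (0.248) lost their calls with the set as a term. Stfa1, Npr3 and Afap1l1 lost theirs with limma-voom, and Slc16a3 and Nkd2 with only the compared genotypes in the fit.

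Glycolysis genes fell in 5 of 18 cases and rose in none between RE and WT (12 and 0 adjusted over the list alone), with Tpi1 (ENSMUSG00000023456) at -0.37 ± 0.06, Aldoa at -0.36 ± 0.07 and Pkm at -0.27 ± 0.07. By fry, glycolysis alone was called between RE and WT (adjusted p = 0.00601). Camera gave an adjusted p of 1.9e-10 (adjusted p = 0.0844 with an estimated correlation) and 8.53e-07 with the set as a term. Aldoa (0.08) and Pkm (0.456) lost their own calls with that term. Camera also called cholesterol synthesis (0 of 19 raised, 11 adjusted over the list alone, 7.83e-08, and adjusted p = 0.681 with an estimated correlation) and spinous keratinocytes (2 of 16 raised, 2 adjusted over the list alone, 1.97e-06, and adjusted p = 0.681 with an estimated correlation) as higher. It called skeletal muscle (0 of 9, 0, 3.21e-05, and adjusted p = 0.537 with an estimated correlation), Langerhans cells and macrophages (0 of 14, 1, 0.0026, and adjusted p = 0.842 with an estimated correlation) and fatty acid synthesis (1 of 9, 1, 0.00862, and adjusted p = 0.842 with an estimated correlation) higher as well. Melanocytes were called lower (0 of 8, 0, 0.0179, and adjusted p = 0.842 with an estimated correlation). The melanocyte call was lost with the set as a term (0.505). That term added oxidative phosphorylation (0.00278), antioxidant (0.00316), granular layer (1.68e-05), stressed keratinocyte (0.00524), fibroblast (0.0386), adipocyte (0.032) and red blood cell genes (0.00286) as higher. Leaving out the 5 libraries in doubt added G2 and mitosis (0.00223) as higher and basal keratinocyte (0.000532) and hair follicle genes (0.0471) as lower. Median and mean had opposite signs for heat shock, glucocorticoid response, oxidative phosphorylation, S phase, interferon response and stressed keratinocytes, of which none passed.

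In total 60 genes were higher and 68 lower in RE than in WT (1138 and 1080 at an unadjusted p under 0.05). Without WT time point 5 replicate 4, which held little Krt14, the counts were 370 and 246. Without RE time point 2 replicate 2 they were 36 and 41, and without time point 4 they were 15 and 7. The count of lower genes was 45 without WT time point 2 replicate 2 and 45 without RE time point 4 replicate 2. With the 5 libraries in doubt left out 379 genes were higher and 327 lower, and these include all 128 genes of the first count. Time point as a factor gave 133 and 195 genes, and a fit of only the genotypes compared 28 and 27. A filter of 5 CPM in 4 libraries gave 37 higher genes, and 42, 41 and 104 were lower with no filter, limma-voom and DESeq2.

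RE against KO showed the clock genes at higher or lower mean levels in the opposite direction to KO against WT. Nr1d1 rose by 3.26 ± 0.34 (adjusted p = 1.66e-11), Nr1d2 by 2.39 ± 0.19 (6.72e-16), Dbp by 1.55 ± 0.27 (1.7e-05) and Ciart by 1.05 (0.00228), while Npas2 fell by 1.86 ± 0.16 (1.88e-14) and Clock by 0.18 (0.00146). The changes were 4.27 for Nr1d1 and 2.18 for Dbp without the 5 libraries in doubt. Other genes higher in RE were Gsdmc (2.18 ± 0.22), Crispld2 (2.13 ± 0.24), Krt2 (2.13 ± 0.15, 11.2 against 2.48 CPM), Ddr2 (1.69 ± 0.18) and Gadl1 (1.62 ± 0.18). Lower in RE were the chemokine Ccl20 (-1.72 ± 0.22), Ttc9 (-1.38 ± 0.10), Epgn (-1.35 ± 0.22, 102 against 258 CPM), the amino acid transporter Slc38a4 (-1.29 ± 0.15), Abhd12b (-1.11 ± 0.12) and fibronectin, Fn1 (-1.09 ± 0.12). In total 1311 genes were higher and 950 lower, and without time point 4 the counts were 833 and 583.

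Lists higher in RE than in KO were clock repressors (7 raised and 1 lowered of 13, 9 and 2 adjusted over the list alone, camera 1.48e-08, and adjusted p = 0.0624 with an estimated correlation) and growing hair shaft (8 and 1 of 15, 10 and 1, 0.000369, and adjusted p = 0.696 with an estimated correlation). So were Langerhans cells and macrophages (4 and 0 of 14, 4 and 0, 0.000686, and adjusted p = 0.696 with an estimated correlation), sebaceous gland (6 and 0 of 12, 9 and 0, 0.00202, and adjusted p = 0.696 with an estimated correlation) and interferon response (5 and 1 of 21, 5 and 1, 0.0352, and adjusted p = 0.739 with an estimated correlation). The hair keratin Krt31 (1.39 ± 0.24), the macrophage gene Cd68 (0.65 ± 0.10), the melanocortin receptor Mc5r (0.72 ± 0.17) and Bst2 (0.64 ± 0.10) led these lists. Lower were cholesterol synthesis (0 and 3 of 19, 0 and 4, 0.00161, and adjusted p = 0.696 with an estimated correlation), with Sc5d at -0.22 and Lss at -0.25. Spinous keratinocytes were also lower (0 and 1 of 16, 0 and 1, 0.00414, and adjusted p = 0.696 with an estimated correlation), with Mt4 at -0.56 ± 0.09. Of these lists fry called clock repressors (adjusted p = 1.66e-09) and growing hair shaft (0.00971) and none of the others. Fry also called antioxidant genes higher and clock activators lower (0.00971 each). The interferon call by camera was lost without the 5 libraries in doubt (0.112). Camera then called clock-linked outputs (0.0378) higher and clock activators (0.0378) and granular layer genes (0.00962) lower. Camera's direction went against median and mean for G2 and mitosis (median 0.03), p53 targets (0.01) and fibroblasts (0.34). Median and mean had opposite signs for fatty acid oxidation, oxidative phosphorylation, glycolysis and the unfolded protein response, of which none passed.

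Of the 2093 genes lower in KO than in WT, 993 were also higher in RE than in KO, and of the 1666 genes higher in KO 685 were lower in RE than in KO. Independent lists would share 148 and 85 genes, and groups simulated without any effect shared 0 on average over 20 simulations, in which at most 0.15 genes were called on average in any direction, so that this 0 does not show what the shared libraries add. Both comparisons use the KO libraries. With KO replicates 1 and 2 set against WT and 3 and 4 against RE, 414 and 287 genes were shared, against 36 and 20 for independent lists, and with the replicates exchanged 379 and 262, against 39 and 23. Over 2229 genes called in replicates 1 and 2, the change from WT measured in the other replicates had a slope of 0.794 in KO and 0.121 in RE. By these slopes 15.2% of the difference remained in RE, and with the replicates exchanged 11.6% remained over 1116 genes. These shares used all libraries, those in doubt included, and no term for the sets. At time point 4 KO and RE lie in another set than WT, so part of what remained can come from the sets.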

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

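The tests of the 3 libraries of time point 3, of time of day and of the processing set as the whole cause of the KO rhythms were chosen only after the result was seen, as were all fits with a processing set or without libraries in doubt.

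The library labelled KO time point 3 replicate 1 lay far from the other 3 of its group in Arntl (21 CPM), Nr1d1 (253 CPM), Dbp (132 CPM) and Npas2 (6.44 CPM). Incomplete silencing would place it between the groups, and its position of -0.0338 between WT (0) and KO (1) argues against that. A mislabelled sample stays open, since -0.0338 is where a WT or RE library would lie. Between WT (0) and RE (1) this library lay at -0.0734. That is inside the range of the WT libraries not in doubt (-0.388 to 0.541) and below that of the RE libraries (0.338 to 1.28). The libraries labelled WT and RE time point 3 replicate 2 differed by 1 in position between WT (0) and RE (1), in the direction opposite to their labels, which an exchange of the 2 could give. No other biological explanation was tested for these libraries.

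The 32 libraries with little mt-Co1 relative to mt-Nd1 include no library of WT time point 4, while KO and RE time point 4 belong to them. All 4 libraries of WT time point 4 lay in the first set, which argues against time of day as the cause. Reads shared between paralogs or pseudogenes and counted differently in the sets may contribute. Genes with many shared words made up 30.5% of the genes that moved at least 2-fold with the set and 17% of the others, a ratio of 1.79, which decides nothing alone. Pseudogenes made up 18.4% of the former and 6.54% of the latter, but they were not the measure set for this explanation. For the rhythmic genes in KO, the processing set as the whole cause is argued against by the 14.3% of genes with an unadjusted p under 0.05 among time points within a set, and how much of the count of 1425 comes from the sets stays open.

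Of 20 clock genes 16 varied more between RE than between WT libraries of a group once the 5 libraries in doubt were left out. The median ratio of SDs was then 1.22, against 1.13 with all libraries, which lay between the bounds set for and against mislabelled samples, so these stay open. A wider spread of all genes in RE stays open, since 90.7% of 10000 random lists had a lower ratio. Mice at different phases of the clock may also contribute, as activators and repressors moved oppositely within RE groups (n = 22, Pearson's r -0.896, permutation p = 0.00012, adjusted 0.00036, and Spearman's rho -0.913, permutation p = 2e-05, adjusted 0.00012, among 6 relations). Without the 2 farthest libraries r was -0.855, within the sets it was -0.657 and -0.945 (n = 11 each), and WT gave -0.608 (rho -0.608, permutation p = 0.0182 and 0.0164, adjusted 0.0254 and 0.0246), a difference between genotypes that was not tested. KO went the other way, with r 0.617 (n = 23, rho 0.403, permutation p = 0.0212 and 0.0956, adjusted 0.0254 and 0.115).

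Other single libraries far from their group were WT time point 6 replicate 1 in Nr1d1 (38 CPM), WT time point 1 replicate 1 in Per2 (11.1 CPM), RE time point 1 replicate 4 and RE time point 5 replicate 3 in Krt14 (2890 and 343 CPM), and WT time point 5 replicate 4 and RE time point 5 replicate 3 in the share of mitochondrial reads (3.29% and 2.78%). Over the measures tested in each of the 18 groups, 10 of 126 tests found such a library, where chance gives 6.3. Several of the 10 come from the same library and are not independent, so this comparison decides nothing.

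Rhythms differed between genotypes in 249 genes for KO against WT and in 5 for RE against WT by the test of the difference. For KO against WT the adjusted p was 4.26e-07 for Arntl, 0.00031 for Npas2, 8.09e-08 for Per2, 0.00297 for Per3, 0.00419 for Cry1, 2.91e-08 for Cry2, 0.0396 for Dbp, 7.79e-06 for Tef and 0.0396 for Ciart. Outside the clock it was 3.55e-06 for Sod2, 3.4e-05 for Rfx5, 3.4e-05 for Rabl6, 6.44e-05 for Mtrr, 0.000103 for Acadl, 0.000134 for Mthfd1l, 0.000161 for Sec22c, 0.000206 for Ttc9, 0.000315 for Pus7 and 0.000908 for Stxbp4. For RE against WT it was 0.0165 for Ltf and 0.0316 for Krtap11-1.

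Chance was set against each count with 100 splits of the libraries, the real one included. Rhythm counts of 6332 in WT, 1425 in KO and 2494 in RE were reached by 1 split each, the real one, with 1755, 3 and 14 as the highest other. The rhythm difference of 249 genes between KO and WT was reached by 1 split (highest other 180), the 1666 genes higher and 2093 lower in KO than in WT by 1 each (2 and 7), and the 1311 higher and 950 lower in RE than in KO by 1 each (8 and 19). No other split drawn reached these counts, which argues against chance for them. Splits of the time points also break up the processing sets. For the rhythm counts they therefore do not tell a daily rhythm from a step between the sets. For the 249 genes the margin is small, since that count was 132 without WT time point 4 replicate 3. The 60 genes higher and 68 lower in RE than in WT were reached by 2 splits each, the real one included. This is rare among the splits, but the highest other splits called 392 and 1006, so chance is not excluded for them. What gave those large counts was not tested. The 5 genes of the rhythm difference between RE and WT were reached by 19 splits (highest other 70), so chance is not excluded. For the 0 genes between RE and KO the comparison says nothing, since each of the 100 splits reaches 0 by construction (highest other 9). The retained counts of 1984 in RE and 1146 in KO were reached by 1 split each (highest other 0), but splits with few rhythmic genes cannot share many, so this adds nothing to the test of the rhythms.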

How the results depend on the processing

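Alternatives without libraries in doubt or time point 4, with the processing set as a term, within a set, and with replicate blocks within each time point were chosen only after the result was seen. With DESeq2 size factors in place of TMM no count moved by more than 1.5 times, and of 1416 values of named genes 4 gained and 0 lost a call. Losses among named genes were 3 with DESeq2, 79 with limma-voom, 43 with no filter, 43 with only the genotypes compared, 9 with the replicate block and 167 with the processing set as a term. Gains were 39, 14, 0, 46, 7 and 27. No direction changed in these. Without the 5 libraries in doubt 123 gained and 15 lost a call. The range of Slbp in KO was 0.68 with the set as a term and the 5 libraries left out, with its peak moved by over 1.5 time points. Depth limits genes near the filter, and 29 list genes lay below it. The cause was not tested for any change except where fewer genes, fewer libraries or a stricter threshold by construction leave fewer calls.

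With no filter the rhythm difference RE against WT was 3 genes, and 42 were lower in RE than WT. The strict filter, which tests fewer genes, gave rhythms for 855 in KO and 1531 in RE, retained rhythms for 1317 in RE and 736 in KO, 1 rhythm difference RE against WT, 37 higher in RE than WT and 836 higher in RE than KO. Limma-voom gave 2 rhythm differences RE against WT and 41 genes lower in RE than WT, the older robust fit 2, and DESeq2 gave 386 rhythm differences KO against WT, 22 RE against WT, and 104 genes lower in RE than WT. Time point as a factor gave 541 rhythm differences KO against WT, 336 RE against WT, and 133 higher and 195 lower in RE than WT. Its rhythm differences can include steps between the sets at time point 4. A fit of only the genotypes compared gave 1615 rhythmic genes in RE, 1274 retained in RE, and 28 higher and 27 lower in RE than WT.

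Leaving out the 2 libraries with little Krt14 gave 630 rhythm differences KO against WT, 22 RE against WT and 1 RE against KO, with 2566 higher in KO than WT, 259 higher and 219 lower in RE than WT and 1590 lower in RE than KO. Leaving out the 3 libraries of time point 3 gave 395 and 35 rhythm differences against WT for KO and RE, with 119 higher and 131 lower in RE than WT. Without all 5 there were 895, 99 and 1 rhythm differences in the same order, 2631 higher in KO than WT, 379 higher and 327 lower in RE than WT and 1625 lower in RE than KO. With the processing set as a term 540 genes in KO and 569 in RE were rhythmic, 514 and 441 retained in RE and KO, 1 rhythm differed RE against WT, and 13 lists were called RE against WT. With that term and without the 5 libraries there were 1016 rhythmic genes in RE, 840 retained in RE, 981, 81 and 1 rhythm differences, 317 higher and 290 lower in RE than WT and 1713 lower in RE than KO. Within a set 338 genes in KO and 731 in RE changed, and 411 and 607 without the 5 libraries.

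Without time point 4 there were 31 rhythm differences KO against WT and 0 RE against WT, 778 higher and 1063 lower in KO than WT, 15 higher and 7 lower in RE than WT, and 833 higher and 583 lower in RE than KO. At an adjusted p under 0.01 there were 3619 rhythmic genes in WT and 1363 in RE, 1076 retained in RE, 54 and 1 rhythm differences against WT, 898 higher and 1183 lower in KO than WT, 17 higher and 14 lower in RE than WT, and 753 higher and 562 lower in RE than KO. With a fold of at least 1.5 there were 3228 rhythmic genes in WT and 1645 in RE, 1234 retained in RE, 225 higher and 541 lower in KO than WT, 33 higher and 11 lower in RE than WT, and 412 higher and 179 lower in RE than KO. Peaks within 0.5 time points gave 698 retained in KO. With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons of means. Fry called 8 lists KO against WT, 1 RE against WT and 4 RE against KO.

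With 1 library or 1 replicate number left out, which leaves fewer libraries, the ranges were 3519 to 7069 rhythmic genes in WT, 1350 to 3093 in RE, 1008 to 2356 retained in RE, 729 to 1285 retained in KO, 30 to 411 rhythm differences KO against WT, 0 to 44 RE against WT and 0 to 2 RE against KO. Means ranged from 724 to 2312 higher and 1125 to 2350 lower in KO than WT, 9 to 370 higher and 8 to 246 lower in RE than WT, and 624 to 1429 higher and 440 to 1292 lower in RE than KO. The replicate numbers share only a number by the rule used, which asks every pair to correlate above 0.1, but the values hint at a link at some time points. Over 72 pairs with the same number at the same time point the median correlation of deviations was 0.0582 (others -0.0168), between -0.581 and 0.624, with 31 over 0.1 and 36 best with their own number, where chance gives 18. In 2 of 18 sets of 4 pairs, RE with WT at time points 1 and 2, all 4 were over 0.1 (0.148 to 0.365). With the replicate block 6365, 1406 and 2479 genes were rhythmic in WT, KO and RE, and 240, 6 and 0 rhythms differed. Replicate blocks within each time point gave 462 rhythm differences KO against WT and 8 RE against WT, with 99 higher and 135 lower in RE than WT.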

Other observations

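The tests with the processing set as a term and the values of the 2 libraries with little Krt14 were chosen only after the result was seen. In KO, 2 glucocorticoid response genes had another daily course than in WT. Tsc22d3, a gene induced by glucocorticoids, ranged 2.08 ± 0.29 on the log2 scale over the day in WT with a peak at 4.26 on the time point scale (adjusted p = 4.93e-07), and gave 0.44 ± 0.30 in KO (adjusted p = 0.703) and 0.79 ± 0.29 with a peak at 4.33 in RE (0.128). Fkbp5, a chaperone of the glucocorticoid receptor that is itself induced by it, had its fitted peak at 4.07 in WT (adjusted p = 0.00285), and its rhythm did not pass in KO (0.0752) or RE (0.0814). The rhythm difference between KO and WT passed for both (0.00499 and 0.00447, edgeR, n = 24 per genotype) and was lost with the set as a term. That between RE and KO did not pass for Fkbp5 (0.588). The mean of Fkbp5 fell in KO against WT by 1.07 ± 0.22 (0.000145) and rose in RE against KO by 1.14 ± 0.22. Of the 15 genes of this list 6 were rhythmic in WT (adjusted p = 0.819 by Fisher's test), and 2 differed in rhythm between KO and WT (3 adjusted over the list alone).

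Single genes of lipid oxidation and antioxidant defence differed between KO and WT, while neither list passed by mean level (camera adjusted p = 0.645 and 0.193). Acadl, an enzyme of fatty acid oxidation, ranged 0.71 ± 0.08 in WT (peak 1.13) and 0.06 ± 0.08 in KO, and its mean rose in KO by 0.36 ± 0.04 (adjusted p = 1.93e-11). Prdx6, a peroxidase, fell in KO by 0.34 ± 0.03 (5.06e-13) and rose in RE against KO by 0.39 ± 0.03 (3.1e-15), and the quinone reductase Nqo1 rose in KO by 0.50 ± 0.09 (8.65e-06). Sesn2, a stress-induced gene on the p53 list, passed the rhythm test in the 3 genotypes, with ranges of 2.14 ± 0.36, 1.66 ± 0.36 and 1.97 ± 0.36 in WT, KO and RE and peaks at 1.12, 1.15 and 1.05 (adjusted p 1.54e-05, 0.00208 and 0.000151). Its KO call was lost with the set as a term (1.58, 0.0554) and with limma-voom (1.37).

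The 2 libraries with little Krt14 differed from the other 3 of their groups across layers of the epidermis, in single libraries and therefore without a test. Krt14 was at 274 CPM in WT time point 5 replicate 4, against 4186 ± 542 CPM in the others (SD, n = 3), and at 343 CPM in RE time point 5 replicate 3, against 3944 ± 59.2 CPM. Krt5, its partner keratin, was at 694 and 560 CPM, against 8122 ± 453 and 7385 ± 565 CPM. The suprabasal keratin Krt10 was at 3.33e+04 and 3.56e+04 CPM, against 1.17e+04 ± 595 and 1.39e+04 ± 1994 CPM. By lists, the median log2 difference was -2.64 and -3.00 over 14 basal keratinocyte genes, -3.10 and -2.97 over 23 G2 and mitosis genes, 1.25 and 1.26 over 16 spinous genes and 1.18 and 1.08 over 24 granular layer genes. Lists of other cells also moved, with 0.92 and 1.65 for fibroblasts and 1.7 and 1.58 for red blood cells. Langerhans cells and macrophages gave -1.27 and -1.02, while endothelial cells gave -0.03 and 0.08.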
